A study of Mus musculus with 12 samples.

How the data were processed

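RNA of 6 mouse livers and 6 F9 cell samples, 100 ng each and labelled by in vitro transcription, was measured on Affymetrix mouse arrays. The authors' processing notes name R 3.0.1 and affy 1.38.1 without saying what each was used for, so the summary method, background correction and normalization behind the log2 values are not stated. As deposited, the log2 values of each liver array have a 2%-trimmed mean of 500 on the linear scale and reach down to -3.17, as a scaling of each array by itself gives. As deposited, the log2 values of the 6 F9 arrays share nearly 1 distribution, with trimmed means of 269.7 to 275.6, as a joint normalization gives. A table with all 12 arrays holds the same values (largest difference 0), so liver and F9 were not normalized together and were never compared directly. The number of arrays limits the precision.

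Of 45101 probe sets per array, 932 name several genes and 9211 have no gene symbol in the annotation, and both were left out. The 64 Affymetrix controls, most of them among these, were left out too, which took the 34958 probe sets with 1 symbol to 34945. Of the 34945 used, 34741 were found in the gene table by Entrez identifier, and 0 symbols changed. For each of the 18193 genes the probe set with the highest mean over the 6 arrays of the comparison was tested; 9010 genes have more than 1 probe set. The build behind the array annotation is not named; the mouse assembly GRCm38.p6 was used for names and for which genes neighbour each other, and no coordinates are given.

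The 2 comparisons were livers labelled knockout minus control livers and knockdown minus control F9 cells, each on its own 6 arrays. Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no filter on dim genes), and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Of 43 gene lists, 35 were tested in liver and 24 in F9 (16 of them in both) with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry beside it. The genes passing in both comparisons were counted per direction with Fisher's exact test, one-sided. As an alternative they were counted at an unadjusted p under 0.01 in each, of which the genes lower in both were singled out after the data were seen. Genes with opposite directions were also tested two-sided, a choice made after the data were seen. The comparisons, the lists, the rule for named genes and most alternatives were fixed before the data were examined. That rule takes the 12 highest and 12 lowest log2 fold changes among genes that passed and whose groups did not overlap. Where fewer than 5 passed in a direction, the genes with the smallest p filled up to 5. Sephs1 and Sephs2, up to 4 members of each list with the smallest p, and up to 6 genes per direction called in both comparisons were added. Symbols of unnamed gene models were left out.

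The procedure was tested on simulated data: 200 of the 18193 genes were given a change of 0.5, 1, 2 or 4 log2 units. In liver 0%, 2%, 42% and 72% of them were called, with 4 false calls, and in F9 74%, 100%, 100% and 100%, with 7 false calls. A simulated list shifted by 1 log2 unit was called in each comparison, with 0 other lists called. That shift was larger than the median of any list called in the data, at most 0.50 in size. Whether shifts of the size seen are found was therefore not tried. The simulated genes were independent of each other, while the estimated correlations in the called liver lists were 0.12 to 0.53. The simulation therefore does not show how often camera calls unchanged lists of correlated genes.

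Alternatives were a replicate block, each array left out in turn, quantile normalization, centring on the median, filters that leave out the dimmest 25% or 50% of genes, the mean of a gene's probe sets, an intensity trend with a robust prior, array weights, each probe set tested by itself, other thresholds, and the other set tests. Neighbouring genes were scanned in windows of 25 genes of the brighter part of F9 expression after the data were seen. The hybridisation and poly-A controls were averaged per array and compared by exact permutation, two-sided.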

Results

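Gene expression was measured on 12 Affymetrix mouse arrays of 45101 probe sets each, in 4 groups of 3. Livers of 3 control mice and 3 mice with a hepatocyte-specific (Alb-Cre) knockout of selenophosphate synthetase 1 (SPS1, gene Sephs1) were taken from males at 3 months of age. F9 cells, a mouse embryonal carcinoma line, were measured as 3 control samples and 3 samples with an shRNA against Sephs1. The design names 3 liver mice per group. Nothing in the labels says that the F9 samples were separate cultures, so the F9 p-values measure only the spread between these samples. After 1 probe set per gene was chosen, 18193 genes were tested in each comparison. Pairs of liver arrays of the same group correlated at r = 0.925 to 0.932 across genes, and pairs from different groups at 0.922 to 0.929. The F9 pairs correlated at 0.995 to 0.998 within groups and at 0.992 to 0.996 between groups. Genes are not independent replicates. The median SD within groups was 0.33 (log2) in liver and 0.11 in F9, and was 0.70 for the dimmer and 0.18 for the brighter genes of the liver. In simulated changes of 1 log2 unit with 3 arrays per group, limma called 2% of the changed genes in liver and 100% in F9. The hybridisation controls, spiked into every sample, were 0.66 higher on the knockout than on the control liver arrays. The poly-A controls were lower on the knockdown than on the control F9 arrays (-1.003).

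The liver comparison asked which transcripts differ when hepatocytes lack Sephs1. Livers labelled knockout had less of the Glrx transcript, which encodes glutaredoxin 1, a small oxidoreductase that uses glutathione (11.02 ± 0.24 in control and 5.58 ± 0.40 in knockout livers, log2, SD, n = 3 each; -5.44, SE 0.25, adjusted p = 0.022, limma). Tmem176a fell by 3.77 (SE 0.19, adjusted p = 0.022) and Tmem176b, which encodes a related membrane protein, fell by 2.40 (SE 0.18, adjusted p = 0.046). Nr1i2, which encodes the xenobiotic receptor PXR, fell by 3.56 (SE 0.20, adjusted p = 0.027), and Mvp, which encodes the major vault protein, fell by 1.93 (SE 0.14, adjusted p = 0.043). Tbx5, a T-box transcription factor gene, rose by 2.94 from a dim control level of 4.11 (SE 0.18, adjusted p = 0.027). Celf6, which encodes an RNA-binding protein, rose by 1.85 from a dim control level of 3.26 (SE 0.12, adjusted p = 0.029). By the rule for named genes, all 3 knockout livers lay on the same side of all 3 controls in each, as in 14.8% of all genes tested (10% by chance).

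These genes make up 7 of the 8 that passed in the liver, 2 higher and 6 lower. The remaining gene, the potassium channel gene Kcnma1, fell by 2.37 (SE 0.15, adjusted p = 0.027) in its brightest probe set, while its other 4 probe sets were 0.53 to 2.68 higher in knockout livers. All 5 are dim, and their mean gave 0.69. The second probe set of Glrx differed by -5.36, that of Nr1i2 by -5.15 and that of Mvp by -3.28. The second, dim probe set of Tbx5 differed by 1.02, and with the mean of its probe sets (1.98) Tbx5 did not pass. Among genes with higher values, Tnf (2.96, adjusted p = 0.097), Scrt1 (2.02, adjusted p = 0.120) and Pkmyt1 (1.81, adjusted p = 0.120) came next by p-value without passing; the mean of the probe sets of Scrt1 gave 1.27. The largest difference of a bright gene that did not pass was in Serpinf1, which encodes the secreted serpin PEDF: 14.39 ± 0.11 in control and 8.45 ± 1.12 in knockout livers (-5.93, SE 0.57, adjusted p = 0.097). Serpinf1 was singled out after its values were seen.

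Sephs1 itself was not lower in the livers labelled knockout: 9.84 ± 0.10 in control and 10.03 ± 0.13 in knockout livers (0.19, SE 0.14, 95% interval -0.15 to 0.53, adjusted p = 0.789), with its 4 probe sets 0.19 to 0.47 higher. The labels do not say which part of the gene was deleted, and a probe set outside that part does not check the knockout. Sephs2, the paralog that makes selenophosphate, was 14.47 ± 0.06 in control and 14.62 ± 0.06 in knockout livers (0.16, SE 0.12, adjusted p = 0.796); its sign turned under quantile normalization (-0.02) and with the mean of its probe sets (-0.01).

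**Figure D1:**
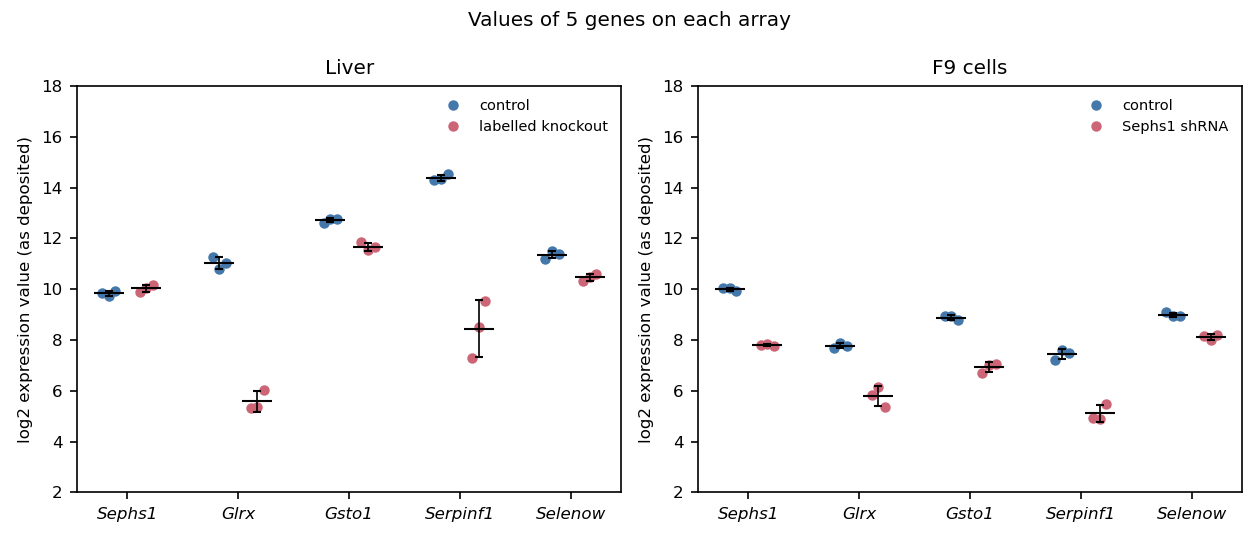
Log2 expression values as deposited (vertical axis) of 5 genes (horizontal axis) on each of the 6 liver arrays (left) and 6 F9 arrays (right). Points are single arrays, and bars are the group mean with its SD (n = 3). Sephs1 averaged 9.84 and 10.03 in the liver groups and fell from 10.003 to 7.799 in F9, while Glrx was lower on all 3 arrays of the treated group in each panel.

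Of the 35 gene lists tested in the liver, 7 differed from the other genes by camera with its preset correlation. The interferon response genes were lower: 17 of 18 measured members had negative values, with a median of -0.40 (adjusted p = 5.3e-05; adjusted p = 0.743 with an estimated correlation). Oasl1, a member of the oligoadenylate synthetase family, differed by -0.67 (SE 0.13). It was the 1 member lower when adjusted over the list alone, and 0 passed over all genes in limma, with 2 at an unadjusted p under 0.05. The Kupffer cell and macrophage markers were lower as a list, 13 of 15 negative with a median of -0.26 (adjusted p = 0.018; adjusted p = 0.743 with an estimated correlation). Csf1r, the receptor of colony-stimulating factor, had -0.39 (SE 0.20; -0.25 without knockout array 2 and -0.22 with the mean of its probe sets), and 0 members passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05 in limma. The Kupffer list was not called after quantile normalization (median -0.26, adjusted p = 0.059), nor without control array 1 (adjusted p = 0.109), control array 2 (0.189) or knockout array 2 (0.160).

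The genes of xenobiotic metabolism by CAR, PXR and AhR were higher as a list, with 11 of 14 members positive and a median of 0.50 (adjusted p = 0.00059; adjusted p = 0.743 with an estimated correlation). After quantile normalization the median was 0.25 and the list was not called (adjusted p = 0.054). Of these, 5 were higher adjusted over the list alone and 0 over all genes in limma, with 7 at an unadjusted p under 0.05. The cytochrome P450 gene Cyp2c55 had 2.72 (SE 0.32) and the glutathione transferase gene Gstm3 had 1.52 (SE 0.21). Higher lists also included the Nrf2 targets (20 of 25 positive, median 0.22, adjusted p = 0.018; adjusted p = 0.756 with an estimated correlation). In that list Gstm3 was higher and Gsta4 (-1.85, SE 0.39) lower adjusted over the list alone, and 0 passed over all genes in limma, with 4 at an unadjusted p under 0.05. The Nrf2 list was not called after quantile normalization (median 0.16, adjusted p = 0.064), nor without control array 1 (adjusted p = 0.184), knockout array 2 (0.253) or knockout array 3 (0.084). The heat shock and chaperone genes (8 of 9 positive, median 0.43) had an adjusted p = 0.023, and adjusted p = 0.756 with an estimated correlation. Its member Hspb1 had 1.30 (SE 0.34). This list was not called after quantile normalization (median 0.36, adjusted p = 0.073), nor without control array 2 (0.077) or 3 (0.103) or knockout array 2 (0.157) or 3 (0.181). The unfolded protein response genes (13 of 17 positive, median 0.09) had an adjusted p = 0.013, and adjusted p = 0.743 with an estimated correlation. Creld2, which encodes an endoplasmic reticulum protein, had 0.92 (SE 0.18). The call ended after quantile normalization (median 0.11, adjusted p = 0.057), and without control array 1 (0.054), knockout array 2 (0.055) or knockout array 3 (0.121). The hepatocyte function genes (12 of 14 positive, median 0.24) had an adjusted p = 0.0092, and adjusted p = 0.743 with an estimated correlation. Ttr, the transthyretin gene, had 0.41 (SE 0.14), or 0.05 after quantile normalization. The call ended after quantile normalization (median 0.03, adjusted p = 0.983), and without control array 1 (0.109) or knockout array 3 (0.064). For comparison, the brightest 0.5% of all genes had a median of 0.29. In these last 3 lists 0 members passed in limma over all genes or adjusted over the list alone, with 2, 6 and 3 members at an unadjusted p under 0.05.

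The glutathione and glutaredoxin list was not called (adjusted p = 0.654; median 0.07, or 0.03 after quantile normalization, mean -0.07), but it holds Glrx, the 1 of 27 members that passed over all genes. Adjusted over the list alone, 3 members were higher and 2 lower, among them Gstm2 (1.05, SE 0.15) and the omega-class glutathione transferase gene Gsto1 (-1.05, SE 0.14, adjusted p = 0.168 over all genes). The selenoproteins were not called (adjusted p = 0.070, 19 of 23 positive, median 0.16, or 0.10 after quantile normalization), nor were the selenoprotein synthesis factors (adjusted p = 0.798, median -0.03, mean 0.03). Selenow, which encodes a small selenoprotein, had -0.90 (SE 0.15, adjusted p = 0.235), and -0.44 in its second probe set. It was the 1 selenoprotein lower adjusted over the list alone. Vitamin B6 metabolism was not called (adjusted p = 0.225). Its member Alpl, the alkaline phosphatase gene, had 0.85 (SE 0.19) and was higher adjusted over the list alone. Among the genes that neighbour Sephs1 on chromosome 2 (adjusted p = 0.210), Celf2 (-1.93, SE 0.22; -0.70 with the mean of its probe sets) and Camk1d (-1.04, SE 0.21) were lower adjusted over the list alone. In the bile acid list (adjusted p = 0.953; median 0.07, or -0.01 after quantile normalization, mean -0.09) the transporter gene Slco1a4 was lower adjusted over the list alone (-3.19, SE 0.29, adjusted p = 0.097 over all genes).

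In limma 8 genes passed at an adjusted p under 0.05, against 1325 at an unadjusted p under 0.05 where chance gives 910. Without any 1 of control arrays 1, 2 and 3 or knockout arrays 1 and 2 the count was 0 (1102 to 1347 at an unadjusted p under 0.05), without knockout array 3 it was 3, and after quantile normalization it was 2, Glrx and Tmem176a. Of the 8 genes 0 passed with the replicate number as a block, 5 after median centring (Celf6, Tmem176b and Mvp did not), 6 with an intensity trend (Celf6 and Kcnma1 did not) and 1, Tmem176a, with the mean of probe sets. None of the 7 lists was called with an estimated correlation or by fry (of these 7, 0 and 2 had an unadjusted p under 0.05, and of all 35, 0 and 5), quantile normalization left the interferon list called (median -0.38), and the count was 11, 3 and 4 without knockout array 1, 2 and 3.

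The F9 comparison asked which transcripts differ when an shRNA lowers Sephs1. Sephs1 fell from 10.003 ± 0.058 in control to 7.80 ± 0.04 in knockdown cells (log2, SD, n = 3 each), a 4.61-fold decrease (SE 0.07, adjusted p = 1.3e-05, limma), and its 4 probe sets gave -2.20 to -0.93. Pmaip1, which encodes the pro-apoptotic protein Noxa, rose by 2.49 from a dim control level of 3.99 (SE 0.13, adjusted p = 8.5e-05). Meis2, a homeobox gene, rose by 2.12 (SE 0.10, adjusted p = 7.5e-05). Vwa5a fell by 2.596 (SE 0.123, adjusted p = 6.9e-05), although its second, dim probe set gave 0.05. Serpinf1 fell by 2.33 (SE 0.17, adjusted p = 0.00032), Glrx by 2.00 (SE 0.18, adjusted p = 0.00065) and Gsto1 by 1.96 (SE 0.11, adjusted p = 0.00014). The second probe set of Serpinf1 gave -0.89. Sephs2 was 11.20 ± 0.11 in control and 11.31 ± 0.05 in knockdown cells (0.12, SE 0.08, adjusted p = 0.474).

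In all, 1310 genes passed in F9, 465 higher and 845 lower, and 94 of them differed more than 2-fold (22 higher, 72 lower). The other 10 genes with the largest rises were Ahnak2 (1.83), Eprn (1.69), the linker histone gene H1f2 (1.69), the imprinted long non-coding RNA Rian (1.59), Nexmif (1.376), Zfhx3 (1.31), Serpinb6c (1.23), Gsx2 (1.22), Zmat4 (1.18) and Spink10 (1.16). Ahnak2 and Rian lie in a distal segment of chromosome 12 whose genes were higher as a whole (median 0.28 over 122 brighter genes). Among the 12 largest falls were also Calml4 (-2.39), the homeobox gene Crxos (-2.10), Ikbkb, which encodes a kinase of the NF-kappa-B pathway (-1.87), Mtmr11 (-1.83), the carboxypeptidase E gene Cpe (-1.80), Pus7l (-1.75) and Nkx6-3 (-1.69). The other 4 probe sets of Ikbkb differed by -0.61 to -0.09. The second, dim probe sets of Crxos (-0.01), Mtmr11 (-0.14) and Cpe (-0.05) hardly differed. With the mean of probe sets the values were -0.56 for Ikbkb, -1.27 for Vwa5a, -1.05 for Crxos, -0.99 for Mtmr11, -0.92 for Cpe, 1.03 for Rian, 0.67 for Nexmif and 0.53 for Zmat4, and each of these genes still passed.

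The p53 target genes were higher as a list in the knockdown cells, with 20 of 22 members positive (median 0.25, adjusted p = 1.1e-10 by camera; adjusted p = 0.038 with an estimated correlation). Of these 7 rose and 0 fell over all genes, and 10 rose adjusted over the list alone. Besides Pmaip1, Plk2 rose by 0.72 (SE 0.07; 0.41 with the mean of its probe sets), Trp53inp1 by 0.71 (SE 0.07) and Eda2r by 0.60 (SE 0.06). The pluripotency genes were higher as a list, with 15 of 20 positive and a median of 0.12 (adjusted p = 0.0038; adjusted p = 0.354 with an estimated correlation). Of these 3 rose over all genes, Tcl1 (0.72, SE 0.08), the orphan nuclear receptor gene Esrrb (0.63, SE 0.08) and Gdf3 (0.39, SE 0.06), and 6 adjusted over the list alone. Gdf3 did not pass without knockdown array 2 (adjusted p = 0.051) or with the replicate number as a block (0.052). Tcl1 and Esrrb lie in the chromosome 12 segment, and without that segment the list was not called (adjusted p = 0.056, within a range of 0.00061 to 0.354 over all settings).

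The selenoprotein synthesis factors were lower as a list, with 9 of 11 negative and a median of -0.14 (adjusted p = 0.0038; adjusted p = 0.258 with an estimated correlation). By camera the list was not called without Sephs1 (adjusted p = 0.082) or without the dimmest 50% of genes (0.125). Over all settings the adjusted p ranged from 0.00032 by fry, which tests a list against no change, to 0.258 by camera with an estimated correlation. Of these 3 fell over all genes and 5 adjusted over the list alone. Besides Sephs1 they were the receptor genes Lrp2 (-1.02, SE 0.10) and Lrp8 (-0.52, SE 0.07), whose products take up selenoprotein P. The selenoproteins themselves were not called as a list by camera (adjusted p = 0.567, median -0.03), while fry called them lower (adjusted p = 0.0081). Of them 1 rose and 3 fell over all genes, and 2 rose and 5 fell adjusted over the list alone. Selenow fell by 0.86 (SE 0.08, adjusted p = 0.00095), Gpx2 by 0.51 (SE 0.06, adjusted p = 0.0031) and Selenop by 0.40 (SE 0.09, adjusted p = 0.030), while Selenos rose by 0.39 (SE 0.08, adjusted p = 0.025). The second probe set of Selenow gave -0.35. Selenos did not pass without control array 2 or any 1 of the knockdown arrays 1, 2 and 3 (adjusted p = 0.064 to 0.1002), with the mean of its probe sets (0.35, adjusted p = 0.079) or with the replicate number as a block (0.060). Selenop did not pass without control array 2 or 3 or any 1 of those knockdown arrays (adjusted p = 0.052 to 0.093), nor with that block (0.080).

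In the glutathione and glutaredoxin list (adjusted p = 0.133, median -0.07), 6 of 27 members fell and 1 rose over all genes, and 8 fell and 2 rose adjusted over the list alone. Besides Glrx and Gsto1, Gstk1 fell by 0.65 (SE 0.09) and Gclc, which encodes the catalytic subunit of the first enzyme of glutathione synthesis, fell by 0.41 (SE 0.07). Gclc did not pass without control array 2 (adjusted p = 0.055) or knockdown array 2 (0.067), nor with the replicate number as a block (0.059). Without the chromosome 12 segment the glutathione and glutaredoxin list was called by camera (adjusted p = 0.031). Over all settings its adjusted p ranged from 0.0020 by fry, a test against no change, to 0.354 by camera with an estimated correlation. In vitamin B6 metabolism (adjusted p = 0.131) 2 of 4 members fell over all genes, Alpl (-0.85, SE 0.14) and the pyridoxal phosphatase gene Pdxp (-0.49, SE 0.08), and 3 adjusted over the list alone. Alpl did not pass without knockdown array 2 (0.065). The Nrf2 targets were not called (adjusted p = 0.568, median 0.03): 2 rose and 3 fell over all genes, 4 and 3 adjusted over the list alone, with the carbonyl reductase gene Cbr3 among the rises (0.50, SE 0.09). Cbr3 did not pass without control array 2 (0.061) or knockdown array 2 (0.092) or 3 (0.075).

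**Figure D2:**
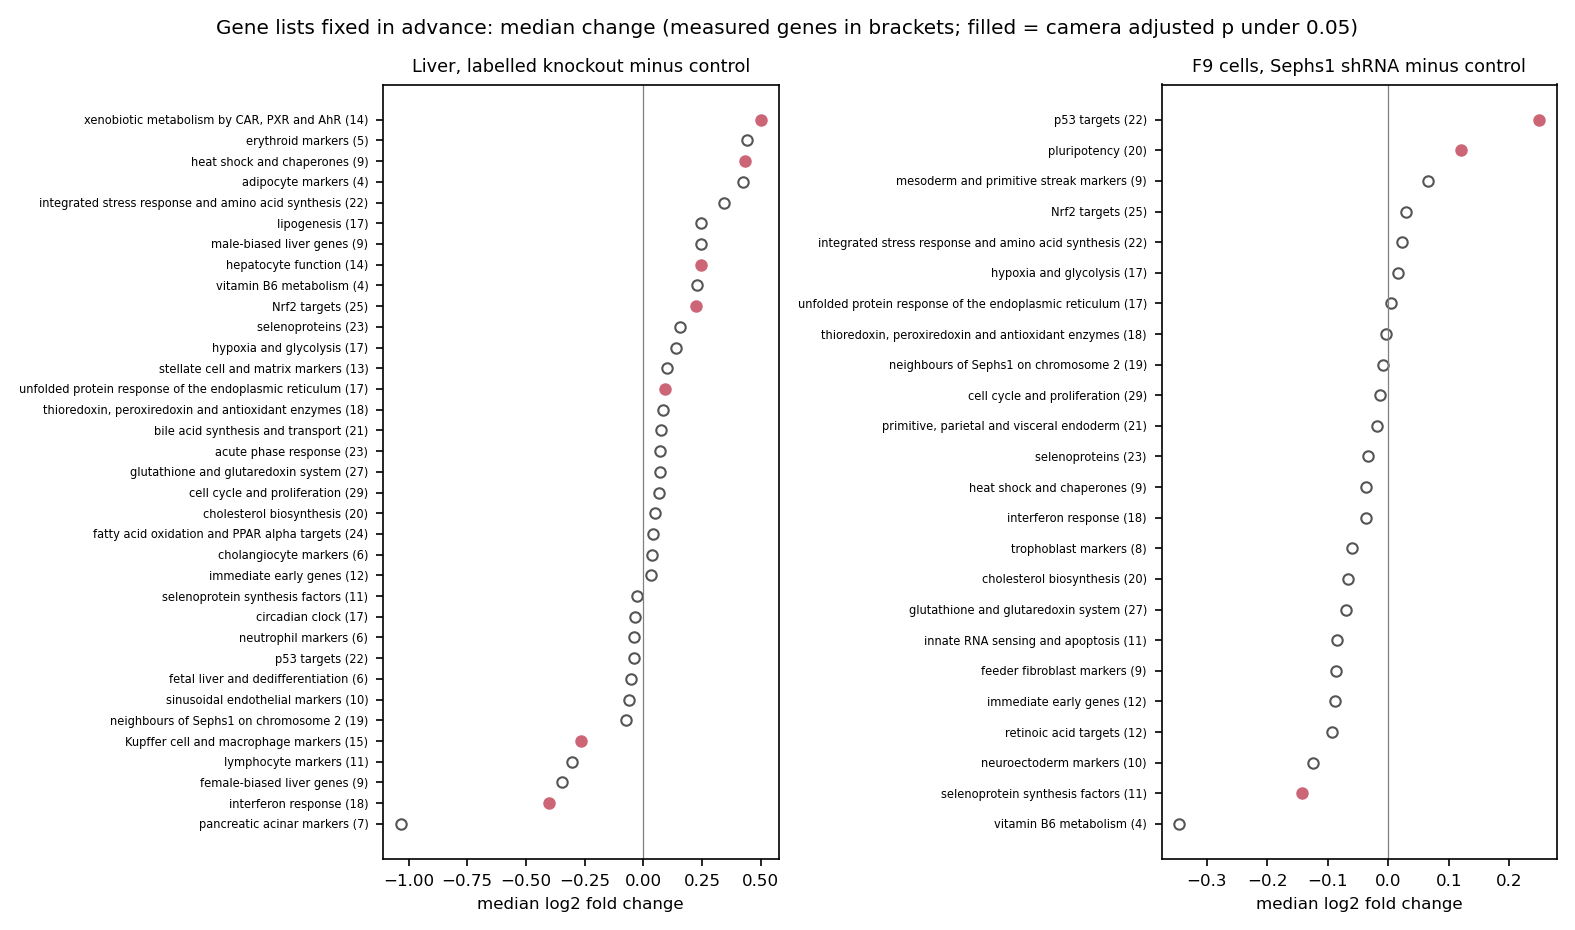
Median log2 fold change (horizontal axis) of each gene list (vertical axis, measured genes in brackets) in liver, livers labelled knockout minus control (left), and in F9, Sephs1 shRNA minus control (right), from 3 arrays per group. Filled points had a camera adjusted p under 0.05 with the preset correlation: 7 of 35 lists in liver, from -0.40 for interferon response to 0.50 for xenobiotic metabolism, and 3 of 24 in F9, with p53 targets at 0.25.

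In limma 3803 genes had an unadjusted p under 0.05 in F9, against 910 by chance, and the groups did not overlap in 27.9% of genes, against 10% by chance. The count of 1310 was 735 and 700 without control arrays 2 and 3, 851, 524 and 665 without knockdown arrays 1, 2 and 3, 662 with the replicate number as a block, 2285 with array weights and 439 at a 1.5-fold change or more.

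Glrx was the 1 gene that passed in both comparisons, lower in each (0.28 expected by the product of the counts, odds ratio 4.11, one-sided Fisher exact p = 0.248), and 0 genes were higher in both (0.05 expected). At an unadjusted p under 0.01 in each limma fit, 45 genes were lower in both against 13.1 expected (odds ratio 4.28, 95% interval 2.99 to 6.04, one-sided Fisher exact p = 1.5e-13), and 10 were higher in both against 6.91 expected (p = 0.155, Fisher exact). Of genes with opposite directions, 12 were higher in liver and lower in F9 against 11.1 expected (two-sided Fisher exact p = 0.754). Fewer than expected, 0 against 8.14, were lower in liver and higher in F9 (two-sided Fisher exact p = 0.00043). Besides Glrx, the genes lower in both included Serpinf1 (-5.93 in liver and -2.33 in F9), Mtfp1, which encodes a protein of mitochondrial fission (-1.91 and -1.65), Ikbkb (-1.43 and -1.87), Gsto1 (-1.05 and -1.96), Vwa5a (-0.89, or -0.43 with the mean of its probe sets, and -2.596) and Selenow (-0.90 and -0.86), all chosen after their values were seen. In the liver none of these 6 passed over all genes (adjusted p from 0.073 for Mtfp1 to 0.402 for Vwa5a), while in F9 each did. Across all 18193 genes the log2 fold changes of the comparisons correlated weakly (Pearson r = 0.05, Spearman rho = 0.03). Genes are not independent replicates, and the comparisons share no control arrays. With the mean of its probe sets Glrx (-5.40 in liver) did not pass in the liver. The count of genes passing in both was 0 without any 1 of control liver arrays 1, 2 and 3 or knockout liver arrays 1 and 2, 2 without knockdown array 3, and 20 without the dimmer 50% of genes. Whether a gene's change differs between liver and F9 was not tested, since their values were normalized separately.

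**Figure D3:**
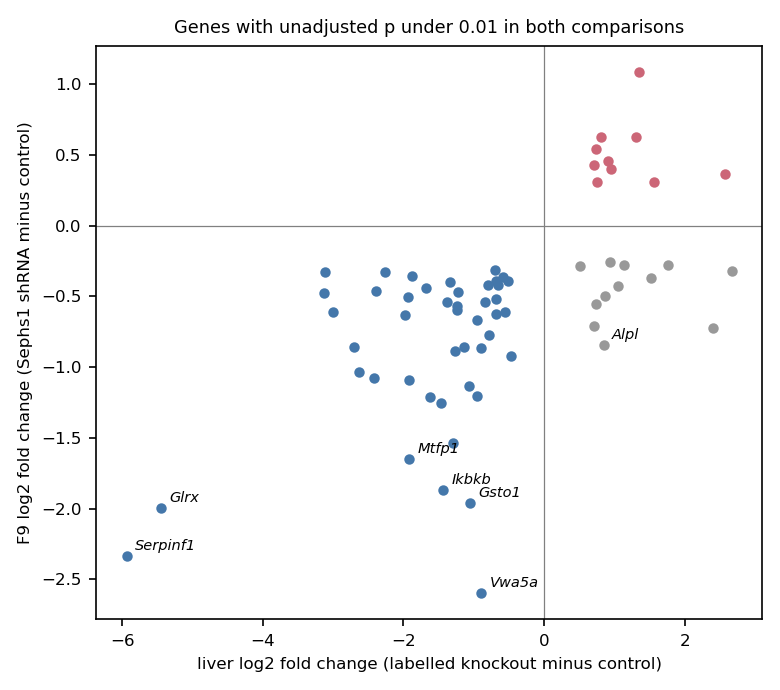
Log2 fold change in liver (horizontal axis, livers labelled knockout minus control) against that in F9 (vertical axis, Sephs1 shRNA minus control) for the 67 genes with an unadjusted p under 0.01 in each comparison, 3 arrays per group. Each point is a gene: 45 lie in the lower left part, 10 in the upper right, 12 in the lower right and 0 in the upper left.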

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

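Chosen only after the results were seen were the tests on splits for the counts of genes, other probe sets, off-target effects, hybridisation controls, quantile-normalized list medians and the imprinted cluster.

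At an unadjusted p under 0.01, 45 genes were lower in both comparisons, where chance gives 13.1. Of 100 joint splits of the liver and F9 arrays, 1, the real one, gave as many (the highest other gave 9). Regrouped F9 arrays gave 0 genes called in F9, so those splits could hardly reach this count. Only the 10 liver splits with the real F9 groups bear on the overlap. They are too few for a share under 0.05, so chance in how the liver arrays were grouped is not excluded. Another bright probe set was present for 16 genes in liver and 18 in F9. Of these probe sets 95% (19 of 20) were lower in the liver and 91.3% (21 of 23) in F9, with medians of -1.03 and -0.47. For these genes as a set this argues against a faulty probe set or a strain variant under it, although only signs were counted. In F9 it stays open for Ikbkb (others -0.12 to -0.09), Galnt4 (-0.09), Yipf1 (-0.08), Smtnl2 (-0.21) and 1700037H04Rik (0.10). In liver it stays open for Cdc14b (-0.17), Zdhhc21 (-0.16), S100a16 (-0.32) and Selenow (-0.44), all at an unadjusted limma p above 0.05. It also stays open for the 29 genes in liver and 27 in F9 without another bright probe set. Effects of the shRNA on other targets alone would leave the overlap at chance, since the livers received no shRNA. The odds ratio of the overlap was 4.28 (lower 95% bound 2.985). This is the overlap that was singled out, and the interval treats genes as independent, so it is no separate test of that explanation. Loss of SPS1 in both systems may account for the shared genes, as a hypothesis found on the same data that rests on livers in which no fall of Sephs1 was seen.

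The liver hybridisation controls, which are added to every sample and belong to no comparison, were 12.93 ± 0.03 on arrays labelled knockout and 12.27 ± 0.23 on controls (log2, SD, n = 3), a difference of 0.6643 (exact permutation p = 0.1, the smallest that 3 against 3 allow). This difference follows the groups, so a hybridisation or scan batch and the knockout cannot be told apart for the 7 called liver lists. The same holds for the 8 genes that passed in the liver and for the liver values of the 45 genes lower in both comparisons. A shift that follows brightness could explain the hepatocyte function list, whose median went from 0.24 to 0.0267 after quantile normalization, but not the interferon list, which stayed at -0.3834. Of the 7 lists, 6 had medians outside 95% of random lists of the same size and brightness, but that bound was wrong for very bright genes. Its brightness classes were too wide there, since the median was 0.29 in the brightest 0.5% of genes and 0.04 in the class below the brightest 1%. The lowest median of any brightness class was -0.006. This argues against a shift by brightness for the 2 lower lists, interferon (-0.40, random lists -0.12 to 0.16) and Kupffer (-0.26, random lists -0.14 to 0.15). Among the 10 splits of the liver arrays 2 gave at least 7 lists, and 1 that was not the real one gave 8. The count of called lists therefore did not set the knockout grouping apart from other groupings. Only the real split gave at least 8 genes (the highest other gave 0), but 10 splits are too few for a share under 0.05.

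In F9, genes of the distal part of chromosome 12, in windows from Ift43 to Sp4, were higher as a set in knockdown cells. Their median was 0.28 (1.21-fold) over 122 brighter genes, 88.5% of them positive. The 3 knockdown arrays had medians of 0.28, 0.30 and 0.30 against the control mean, and the same genes had a median of -0.00 in the liver (89 genes). The rise did not reach the far end of the windows. There Wdr60 (0.03), Esyt2 (0.01) and Ncapg2 (0.01) hardly differed, and Rapgef5 (-0.76), Cdca7l (-0.77) and Sp4 (-0.12) were negative. Ift43 at the near end had -0.003. The rise was not confined to the imprinted cluster: the other 119 genes had a median of 0.2663 (quartiles 0.15 to 0.41). As a test this was fixed in advance, since the segment was chosen by its window medians. For the same reason 10000 random sets of like brightness from outside it, which reached at most 0.0603, decide nothing. A shift that follows brightness is argued against by the brightness classes of all F9 genes, whose medians were -0.02 to 0.004. Extra copies of the segment in the knockdown cells may explain the pattern but were not decided. The test took 49 dimmer genes of the segment, those within the dimmest 50% but above the dimmest 25% of F9 expression. Of these 55.1% were higher, against 48.1% of such genes elsewhere, between the bounds set for the test. DNA was not measured. The segment holds 1.22% of the genes tested, 52 of the 465 that rose (11.2%) and 4 that fell, and whether the shRNA or a difference that arose between the cell populations underlies it stays open.

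Alpl was 0.8504 in liver and -0.8465 in F9, with all 3 treated arrays on opposite sides of their controls; the difference was not tested. Camk1d was -1.0369 in liver and 0.1847 in F9 in the same way, also not tested. Chac1 was 0.5177 in liver and -0.2877 in F9, again not tested. Selenop was 0.37 in liver, or 0.07 after quantile normalization, and -0.4039 in F9, and this difference was not tested either. Groups of 3 were not searched by a formal rule for single arrays far from the others.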

How the results depend on the processing

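Chosen after the data were seen were the fits without the chromosome 12 segment or without Sephs1 in the lists, all settings of the genes lower in both at an unadjusted p under 0.01, single arrays left out for the genes passing in both, and the settings of named genes. In the liver the count of 8 genes was 0 with a replicate block (1240 at an unadjusted p under 0.05), 2 after quantile normalization or with the mean of probe sets, 25 and 67 without the dimmest 25% and 50% of genes (fewer genes tested), 89 with an intensity trend and robust prior, 5 by probe set and 17 at an adjusted p under 0.1; the cause was not tested. It was 0 without any 1 of control arrays 1, 2 and 3 and knockout arrays 1 and 2, and 3 without knockout array 3, a range of 0 to 3. The share of higher genes went from 25% to 0% after quantile normalization and to 16.7% after median centring.

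The 7 liver lists became 1 after quantile normalization, 4 with the mean of probe sets, 12 with the trend, and 0 with an estimated correlation or by fry; the cause was not tested. After quantile normalization the Kupffer (-0.26), heat shock (0.36), unfolded protein response (0.11) and Nrf2 medians (0.16) moved by less than 0.1, while the xenobiotic median went from 0.50 to 0.25 and the hepatocyte function median from 0.24 to 0.03. Leaving out 1 array gave 3 to 11 (11, 3 and 4 without knockout arrays 1, 2 and 3). The 1310 F9 genes became 662 with a replicate block, 2285 with array weights, 439 at 1.5-fold or more and 1993 at an adjusted p under 0.1, and 524 to 1452 without 1 array (735 and 700 without control arrays 2 and 3, 851, 524 and 665 without knockdown arrays 1, 2 and 3). The other settings gave 1161 to 1951. The 3 F9 lists became 1 with an estimated correlation and 9 by fry (2 higher, 7 lower), 3 to 4 without 1 array, and 2 without Sephs1. Those that fry added were all lower: selenoproteins, glutathione and glutaredoxin, vitamin B6, cholesterol biosynthesis, trophoblast markers, and innate RNA sensing and apoptosis. The 1 gene passing in both became 20 without the dimmest 50% of genes, 0 with the mean of probe sets or a replicate block and 55 at an unadjusted p under 0.01, and 0 to 2 without 1 array (0 without control liver arrays 1, 2 or 3 or knockout liver arrays 1 or 2, 2 without knockdown array 3); the cause was not tested.

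Reversed were Kcnma1 in liver (0.6853 with the mean of probe sets), and Sephs2 in liver (-0.0153 after quantile normalization and -0.0109 with the mean of probe sets). For Kcnma1 the mean takes in 4 dim probe sets of the other sign, and for Sephs2 the cause was not tested. Genes lower in both at an unadjusted p under 0.01 stayed within 30 to 46. Sephs1 kept its direction and side of the threshold, at 0.13 to 0.26 in liver and -2.24 to -2.18 in F9 without 1 array. All 24 F9 genes with the largest changes passed in each setting that tested them (16 without the dimmest 50%, 22 without the segment). The replicate numbers were not a pairing: own numbers matched best for 1 of 6 liver and 0 of 6 F9 arrays. Not run, since liver and F9 were not normalized together, were the 12-array table, the fit of all 12 arrays and the test of the difference between liver and F9 with its alternatives. In the liver the median SD was 0.70 for the dimmer and 0.18 for the brighter genes.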

Other observations

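The count of splits for F9 genes and the test of the poly-A controls were chosen after the results were seen. Several lists not yet described held single large changes in F9 without being called as lists by camera. Of them fry, which tests against no change, called 3 lower. These were the trophoblast markers (fry adjusted p = 0.0018), cholesterol biosynthesis (0.0018) and the innate RNA sensing and apoptosis genes (0.039). The trophoblast markers (adjusted p = 0.335 by camera) held Krt8, which fell by 1.18 (SE 0.07), and Krt18, which fell by 0.97 (SE 0.13), the keratin pair of simple epithelia. In this list 2 of 8 members fell over all genes and 2 adjusted over the list alone. The retinoic acid targets (adjusted p = 0.504; median -0.09, mean 0.01) held Meis2, which rose, and Stra8, which fell by 0.78 (SE 0.07), 1 each over all genes, and 1 rose and 3 fell adjusted over the list alone. Of the endoderm genes (adjusted p = 0.766) Sox7 rose by 0.71 (SE 0.07) and 2 fell, with 2 higher and 3 lower adjusted over the list alone. The mesoderm markers (adjusted p = 0.504) held 1 rise, Eomes (0.36, SE 0.08), and the neuroectoderm markers (adjusted p = 0.504) 1 rise, Sox1 (0.83, SE 0.14; 0.43 with the mean of its probe sets). Adjusted over the list alone these were 1 rise, and 1 rise and 1 fall. Eomes did not pass without control array 2 or 3 or knockdown array 1 or 2 (adjusted p = 0.072 to 0.115) or with the replicate number as a block (0.080), nor Sox1 without knockdown array 2 (0.059) or 3 (0.056). The feeder fibroblast markers (adjusted p = 0.504) held 1 fall, Thy1 (-1.41, SE 0.11), also the 1 adjusted over the list alone.

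Among stress and growth genes in F9, Ccnd1, the cyclin D1 gene, fell by 1.09 (SE 0.12), the 1 of 29 cell cycle genes to pass by either adjustment (list adjusted p = 0.726). Hspa1b, an inducible chaperone gene, fell by 1.02 (SE 0.11), the 1 of 9 heat shock genes over all genes, with 1 higher and 4 lower adjusted over the list alone (list adjusted p = 0.544). The innate RNA sensing and apoptosis genes (adjusted p = 0.669) held 1 fall, the BH3-only gene Bcl2l11 (-0.67, SE 0.10; -0.39 with the mean of its probe sets), with 2 higher and 3 lower adjusted over the list alone. The interferon response genes (adjusted p = 0.567) held 1 fall by either adjustment, Bst2 (-0.71, SE 0.10). Of the integrated stress response genes (adjusted p = 0.504) Atf5 (0.51, SE 0.07) and Ddit4 (0.46, SE 0.11) rose and Chac1 fell, with 3 and 1 adjusted over the list alone. Ddit4 did not pass without control array 1 or 2 or any 1 of knockdown arrays 1, 2 and 3 (0.055 to 0.140) or after median centring (0.45, adjusted p = 0.051). Chac1 did not pass without control array 2 or 3 or any 1 of those knockdown arrays (0.094 to 0.110) or with the replicate number as a block (0.116). Of the unfolded protein response genes (adjusted p = 0.726; median 0.00, negative after median centring) 2 rose, among them Sel1l (0.47, SE 0.07), which lies in the chromosome 12 segment that was higher as a whole, and 1 fell, by either adjustment. Hypoxia and glycolysis (adjusted p = 0.669) held Bnip3 (0.63, SE 0.08) and Egln3 (-0.59, SE 0.08), 1 rise and 1 fall by either adjustment. The immediate early genes (adjusted p = 0.669) held Jun (0.90, SE 0.17) and Egr1 (-0.52, SE 0.12), with 1 higher and 2 lower adjusted over the list alone. Jun did not pass without any 1 of knockdown arrays 1, 2 and 3 (0.067 to 0.087), nor Egr1 without any 1 of those or control array 2 or 3 (0.068 to 0.109). Cholesterol biosynthesis (adjusted p = 0.083, 17 of 20 negative) held 1 fall, Dhcr7 (-0.55, SE 0.10), and 4 adjusted over the list alone. Dhcr7 did not pass without knockdown array 2 (0.073). The neighbours of Sephs1 (adjusted p = 0.504) held 1 rise by either adjustment, Fam107b (0.56, SE 0.10; 0.34 with the mean of its probe sets), which did not pass without knockdown array 2 (0.071) or 3 (0.065). The list had a median of -0.01, positive after quantile normalization, and a mean of 0.03. The thioredoxin and antioxidant enzymes (adjusted p = 0.726) held 0 genes by either adjustment in limma, with 2 at an unadjusted p under 0.05.

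In the liver the remaining lists were not called by camera, and 0 members passed over all genes in limma, with 0 to 3 per list at an unadjusted p under 0.05. Where no count is given, 0 members passed adjusted over the list alone. Those with an adjusted p of 0.070 were lipogenesis (median 0.25, or 0.07 after quantile normalization), the integrated stress response genes (0.34), the male-biased genes (0.24, or 0.12) and the lymphocyte markers (-0.31), with 3, 3, 1 and 1 members at an unadjusted p under 0.05. The pancreatic acinar markers had a median of -1.03 (adjusted p = 0.076; adjusted p = 0.756 with an estimated correlation), the erythroid markers 0.44 (0.29 after quantile normalization, adjusted p = 0.152, 1 member higher adjusted over the list alone) and the adipocyte markers 0.42 (0.410). The female-biased genes had an adjusted p of 0.758 with a median of -0.35 and a mean of 0.23, and 2 members were higher adjusted over the list alone, Fmo2 (1.71, SE 0.22, adjusted p = 0.144) among them. The sinusoidal endothelial (-0.06, adjusted p = 0.217), stellate cell (0.10, or 0.06 after quantile normalization, 0.953), cholangiocyte (0.04, 0.953) and neutrophil markers (-0.04, mean 0.01, 0.455) had the medians and adjusted p given. The cholangiocyte median turned negative after quantile normalization. The fetal liver genes had -0.05 (0.953), the immediate early genes 0.03 (0.758), hypoxia and glycolysis 0.14 (0.08 after quantile normalization, adjusted p = 0.576), the cell cycle genes 0.07 (0.758) and the antioxidant enzymes 0.08 (0.455). Cholesterol biosynthesis had a median of 0.05 and camera direction down (0.648), the p53 targets a median of -0.04 and a mean of 0.04 (0.953), and the circadian clock -0.03 and 0.04 (0.963). The acute phase genes had 0.07 and -0.06 (0.953) and the genes of fatty acid oxidation 0.04 (0.953). The medians of both turned negative after quantile normalization.

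In F9 the real split of the 6 arrays gave 1310 genes and 3 lists, and the highest of the other splits gave 0 genes and 2 lists. Of the 10 splits 1 gave as many genes and 1 as many lists. The 10 splits are too few for a share under 0.05. F9 control array 1 stood apart from the other F9 controls: it lay at -21.43 and 17.55 on the first and second principal components, against -11.56 and -13.12 for control array 2 and -11.24 and -11.00 for control array 3. Its correlation with them was 0.995, against 0.998 between them, and 1452 genes passed without it. The F9 poly-A controls were 6.86 ± 0.60 on knockdown arrays and 7.86 ± 0.27 on control arrays (log2, SD, n = 3 each), a difference of -1.003 (exact permutation p = 0.1, the smallest that 3 against 3 allow). They spanned 6.19 to 7.35 on knockdown arrays and 7.56 to 8.09 on control arrays. This difference follows the groups, and its cause was not tested. That cause and the knockdown cannot be told apart for the 1310 F9 genes and the 3 called F9 lists.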
